A study of Mus musculus with 8 samples.

How the data were processed

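Total RNA of 8 samples of mouse placenta of embryonic day 11.5, with deciduas removed, was labelled with Cy3 and hybridized to 1-colour Agilent arrays, per the labels' protocols. The embryos, from in vitro fertilization, were cultured at 37 °C for 16 h before transfer. The deposited scanner files hold 59305 gene spots each and give intensity values, which Agilent Feature Extraction 10.5.1.1 subtracted for background but did not scale between arrays, per the file headers. The same deposited files hold other columns of 0 or 1 marks per spot (well above background, non-uniform, population outlier, saturated), per the file headers. The deposited value table is on the log2 scale: its values matched the log2 processed signal minus each array's 75th percentile and minus each probe's median over the 8 arrays, a step taken by the authors (r from 0.99988 to 0.999933 per array against the scanner files).

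The arrays were grouped by genotype as the labels give it, 4 wild type and 4 knockout. Control spots and spots marked as outliers were left out, and spots of one probe were averaged. The log2 processed signal was centred on each array's 75th percentile, and the 31631 probes well above background on at least 4 of the 8 arrays were kept. Probes were named through a RefSeq table, which gave a symbol to 27235 of the 55681 probes, while 28446 had none and were counted but not named. The probe with the highest mean over all 8 arrays stood for its gene, which left 26983 genes, 15057 of them with a symbol. The headers place probes on build mm9 and the RefSeq table follows another build, so no coordinates are given.

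Genotypes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05; a size threshold of 2-fold was applied beside it. Sfmbt2 probes also had an exact permutation test over the 70 labellings of the arrays. Of 27 gene lists, the 25 with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists, after 16 genes with a missing value were left out. Where a gene was not well above background on any array of a genotype, its fold is a bound, with each of those arrays set at its lowest well-above-background signal or at its own value where that was higher. Named genes were Sfmbt2, the 10 largest rises and 10 largest falls among called genes whose genotypes did not overlap, up to 4 called members of smallest p per list, and Xist. The test, the lists, the rule for named genes and the alternative settings (other than those named as later in the closing section) were fixed before the data were examined.

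The alternatives were normexp background correction, quantile and median scaling, no filter or a filter on all 8 arrays, other uses of probes, a variance trend, array weights, the deposited table, replicate number or slide as a block, the mean level of Y-linked genes as a covariate, camera with an estimated correlation, fry, and each array left out. Normexp was run on the median spot signal, with an offset of 50. A test for seed sites of the cluster's microRNAs was planned and not run, because no transcript sequence was used here. Tested on simulated changes among 26967 genes, the fit recovered 22%, 56%, 92% and 94% of log2 changes of 0.5, 1, 2 and 3 and called 4 of 26752 unchanged genes. Each size was given to 50 genes, with independent noise and no shift between scan sessions. These rates therefore do not cover a session effect or a change of most genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.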

Results

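Messenger RNA was measured in 8 samples of mouse placenta of embryonic day 11.5, of which 4 were wild type and 4 carried a deletion of the microRNA cluster that lies in an intron of Sfmbt2, a Polycomb-related gene on chromosome 2. The embryos came from in vitro fertilization, were cultured for 16 h and transferred to foster females, and the deciduas were removed before RNA extraction. Each sample was hybridized to a 1-colour array with 55681 probes. Between 52.5% and 55.9% of spots were well above background on the wild-type arrays and between 58.0% and 59.7% on the knockout arrays. The labels do not say whether the replicates came from separate animals, so the p-values measure the spread between these samples, and the number of arrays limits the precision. All 4 knockout arrays lay on 1 slide and were scanned in a session of their own, whereas the wild-type arrays lay on 2 other slides scanned in another session. Genotype and scan session therefore cannot be told apart in any comparison that follows. The median negative control signal was 71.7 ± 5.5 on the wild-type arrays and 36.0 ± 0.8 on the knockout arrays (SD, n = 4 each). The median spike-in signal was 728 ± 35 and 2214 ± 27, respectively. Pairs of arrays correlated at 0.987 to 0.994 within wild type, at 0.985 to 0.993 within knockout and at 0.943 to 0.961 between genotypes, across probes.

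The first comparison was of Sfmbt2 itself, the gene that hosts the deleted cluster. Its brightest probe was lower in all 4 knockout samples, at a log2 level of 4.55 ± 0.17 against 5.08 ± 0.08 in wild type (SD, n = 4 each), where 0 is the 75th percentile of each array. The difference was -0.54 on the log2 scale (SE 0.10, limma adjusted p = 0.0021, exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 arrays allow). The other two Sfmbt2 probes differed by -0.37 (SE 0.17, limma adjusted p = 0.0874) and by -0.095 (SE 0.20, limma adjusted p = 0.689), and did not pass (exact permutation p = 0.114 and 0.686). These probes match exons and do not measure the intronic microRNAs, so they do not check the deletion. The fall of the brightest probe was lost when arrays were scaled to their median, where the difference was 0.07 (limma adjusted p = 0.581), and when the probes were averaged, where it was -0.33 (limma adjusted p = 0.0762). Among the 11 tested genes of the list of Sfmbt2 and its chromosome 2 neighbours, 3 rose and 4 fell. Pfkfb3, a regulator of glycolysis, rose by 1.91 (SE 0.21), Kin fell by 1.03 (SE 0.09) and Itih5 fell by 1.03 (SE 0.11). Atp5c1 was 0.52 higher by its brightest probe and differed by -0.36 by its other probe. The list as a whole did not shift against other genes (camera adjusted p = 0.779), and its median of 0.14 and mean of -0.10 differed in sign. With median scaling 7 of its genes were higher and 2 lower.

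**Figure D1:**
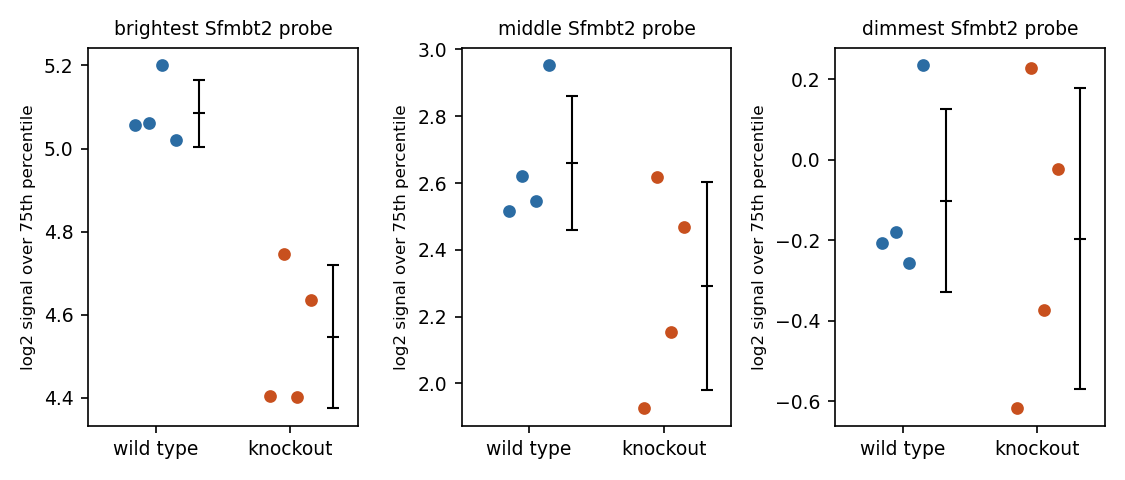
Log2 signal of the 3 Sfmbt2 probes relative to each array's 75th percentile (y axis, a separate scale per panel) in wild-type and knockout samples (x axis). Points are arrays, and bars are the mean and SD of 4 arrays; the knockout mean of the brightest probe was 4.55 against 5.08, and the groups overlapped for the other probes.

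The comparison of all genes asked which transcripts differ without the cluster, the study's stated aim being to find its targets. Of 26983 genes tested, 7116 were higher and 10849 lower in the knockout samples (limma, adjusted p under 0.05), and 2433 and 4807 of these differed by at least 2-fold. The 4 knockout values lay wholly outside the 4 wild-type values for 16651 genes, or 61.7%, where chance gives 2.86%. No session held both genotypes, so no value within a session could be had. Between the slides of the wild-type arrays, 2 arrays against 2, 6 genes differed (2905 at unadjusted limma p under 0.05). Those slides also divide the arrays with and without Y-linked signal, so slide alone was not measured. On the knockout slide, between replicates 3 and 4 and replicates 1 and 2, 0 genes differed (2670 at unadjusted limma p under 0.05). Among the 15057 genes with a symbol, 5434 rose and 4342 fell, whereas 1682 rose and 6507 fell among the probes without one. By mean signal, the median difference was -0.70 in the dimmest of 5 equal groups of genes and 0.13 in the brightest, and 78.1% of the calls were falls in the dimmest and 38.2% in the brightest.

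The largest rise among named genes was that of Gkn2, a gastrokine, at 5.41 on the log2 scale (SE 0.79, adjusted p = 0.00049), or 42.6-fold; it was well above background on 3 of the 4 wild-type arrays, and the difference was 6.08 without wild-type replicate 2. Sfrp5, a secreted Wnt antagonist, rose by 4.11 (SE 0.49), and Prl8a6, a prolactin-family hormone of the placenta, rose by 3.87 (SE 0.74), with signal on all 8 arrays. Tff1, a trefoil factor, and Crabp1, a retinoic acid binding protein, rose by 4.29 (SE 1.1) and 4.24 (SE 0.79), each measured on 1 of the 4 wild-type arrays, or by 4.18 and 3.59 with the wild-type arrays held at no less than their lowest signal above background. The Tff1 difference was 3.56 without knockout replicate 1 or 2 and 5.17 without 3, and that of Crabp1 3.46 without knockout replicate 1. Genes not well above background on any wild-type array had only a bound. Coch was at least 8.74-fold higher, Ccl7, a monocyte chemokine, at least 5.82-fold, the homeobox gene Dbx1 at least 5.35-fold, Sprr2f at least 4.61-fold and Cd5l, a macrophage secreted protein, at least 4.06-fold. Without knockout replicate 1 the bounds of Coch and Sprr2f were 3.23-fold and 1.74-fold, without replicate 3 they were 13.6-fold and 6.95-fold, and without replicate 4 they were 14.0-fold and 8.96-fold. The Coch and Sprr2f calls were lost with normexp background correction (limma adjusted p = 0.0748 and 0.0771) and with the Y-linked covariate (0.0546 and 0.0898). The Sprr2f call was also lost without wild-type replicate 2 (0.0579) or 4 (0.0535) or knockout replicate 2 (0.0551).

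Among the largest falls, Myh8 and Myh4, which encode skeletal myosin heavy chains, were at least 15.4-fold and 9.75-fold lower in knockout, where neither was well above background, and without wild-type replicate 4 the bounds were 10.1-fold and 5.90-fold. Cacna1s, the skeletal muscle calcium channel subunit, fell by 3.58 (SE 0.23, adjusted p = 1.5e-05) and was measured on all 8 arrays. Slc15a2, a peptide transporter, fell by 3.88 (SE 0.93), and 4931408C20Rik fell by 3.54 (SE 0.98), each measured on 2 of the 4 knockout arrays. With the knockout arrays held at no less than their lowest signal above background, the differences were -3.35 and -2.79. Slc15a2 differed by -4.57 without knockout replicate 1 and -2.96 without 4, and 4931408C20Rik by -2.73 without knockout replicate 3 and -4.35 without 4. Also bounded in knockout were Klf17 at 4.79-fold or more, Olfr1344 at 4.65-fold or more, Chia1 at 4.30-fold or more, Dsg1c, a desmosomal cadherin, at 3.81-fold or more and Gm5938 at 3.69-fold or more.

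The direction of the whole comparison depended on the scaling and on the filter. With each array scaled to its median, every difference moved up by 0.61. Then 14411 genes were higher against 4789 lower, so 75.1% of calls were rises in place of 39.6%. The array median was 66.7 ± 5.2 in wild type and 42.9 ± 1.3 in knockout, and the 75th percentile 893 ± 78 and 825 ± 18 (SD, n = 4 each). The median thus lies nearer to background, where the negative controls also differed, which limits median scaling wherever it is given below. For differences of at least 2-fold the share of rises was 33.6%, against 81.3% with median scaling, 53.1% with quantile normalization and 49.6% with normexp. The number of these genes was 7240, and 2905 with normexp. That setting also took the median spot signal and an offset of 50, and these parts were not tested apart. Without the filter on dim probes 7190 genes were higher and 28262 lower, so 20.3% of calls were rises, and 10.7% of those of at least 2-fold. The median difference over all tested genes was then -0.81, against -0.14 with the filter. The genes tested with the filter had a median shift of 0. A list tested without the filter is thus set against a lower range of genes. The deposited value table gave 7384 higher and 10596 lower genes, of which 17711 matched the calls from the scanner files in gene and direction.

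**Figure D2:**
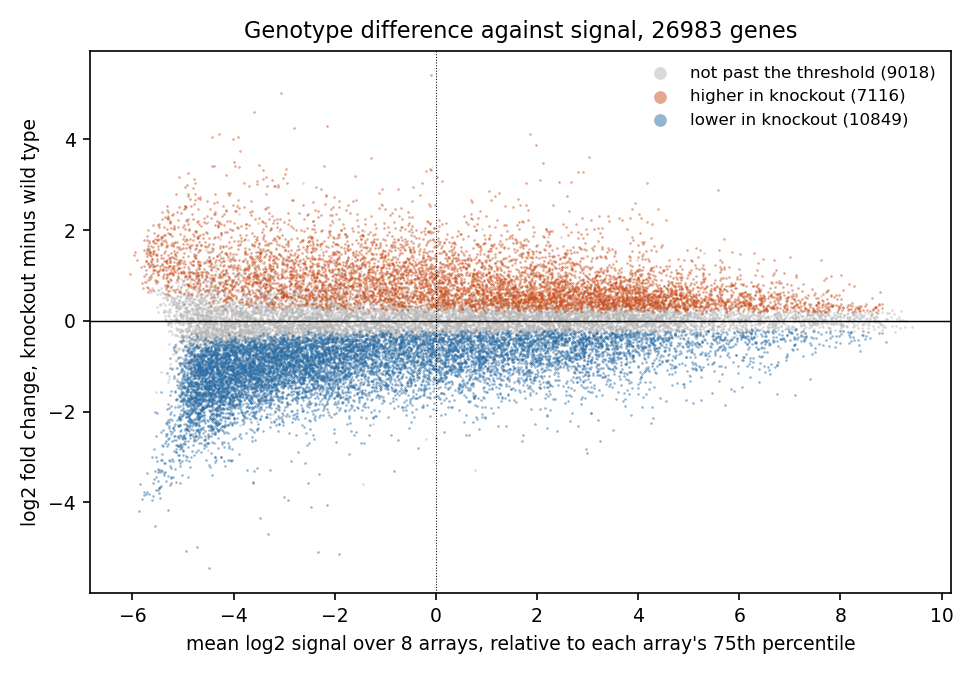
Log2 fold change, knockout minus wild type (y axis), against the mean log2 signal over 8 arrays relative to the 75th percentile (x axis), with 1 point for each of 26983 genes. Orange points are the 7116 higher and blue points the 10849 lower genes; the falls crowd the dim end, where the median of the dimmest group was -0.70, whereas 75.1% of calls were rises with median scaling.

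Lists of marker genes fixed before the data were examined described the cell types of the samples. Of the 15 markers of fetal endothelium, the lining of the vessels of the labyrinth, 13 rose and 1 fell. Cldn5, a tight junction protein, rose by 2.22 (SE 0.17), Tie1 by 2.0 (SE 0.16), Sox18 by 1.97 (SE 0.15), Egfl7 by 1.56 (SE 0.11), Emcn by 1.49 (SE 0.11) and Pecam1 by 1.16 (SE 0.08). The exceptions were Kdr, a VEGF receptor, at -0.38 (SE 0.09) by its brightest probe and 1.38 by the other, and Cdh5 at -0.22 (SE 0.12, adjusted p = 0.129). With median scaling all 15 rose. The list median was 1.33, and the list shifted upward against other genes (camera adjusted p = 1.1e-05, and adjusted p = 0.236 with an estimated correlation). Per array, the endothelial median stood 1.31 ± 0.07 above the wild-type mean in knockout, against a wild-type SD of 0.15 (n = 4 each). Of 14 mesenchyme and pericyte markers, 9 rose and none fell, among them Des, a muscle intermediate filament protein, by 3.34 (SE 0.66), Dlk1 by 1.52 (SE 0.17), Acta2 by 1.13 (SE 0.13) and Pdgfrb by 0.90 (SE 0.15). That list had a median of 1.15 (camera adjusted p = 0.0030, and adjusted p = 0.295 with an estimated correlation). With median scaling 12 of its members rose, but the list did not pass (camera adjusted p = 0.0603).

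Markers of maternal and immune cells also differed with genotype, although the deciduas had been removed from all samples. Of 13 decidual stroma markers 9 rose and none fell, including the transcription factors Hand2 by 2.54 (SE 0.28), Hoxa10 by 2.30 (SE 0.37) and Hoxa11 by 2.20 (SE 0.31), and the chaperone Cryab by 1.97 (SE 0.24). The decidual median was 1.97 (camera adjusted p = 0.00045, and adjusted p = 0.426 with an estimated correlation), and per array it stood between 1.1 and 3.01 above the wild-type mean. With median scaling all 13 rose, but the list did not pass (camera adjusted p = 0.0557). Of 11 macrophage and leukocyte markers 9 rose and none fell, among them Lyz2, lysozyme, by 3.32 (SE 0.47, measured on 1 wild-type array, or 2.52 with those arrays at their lowest signal above background), Tyrobp by 2.35 (SE 0.15), Fcer1g by 1.90 (SE 0.24) and the complement gene C1qa by 1.87 (SE 0.27). Their median was 1.87 (camera adjusted p = 0.00052, and adjusted p = 0.426 with an estimated correlation). The uterine natural killer cell list had a median of 1.35, but Gzmd, a granzyme, was the only member of 11 to pass, at 1.97 (SE 0.67, limma adjusted p = 0.0297), whereas all 11 rose with median scaling. The Gzmd difference was 2.64 without knockout replicate 2. The Gzmd call was lost without wild-type replicate 1 (0.067) or 2 (0.0754) and without knockout replicate 1 (0.0706), 3 (0.0774) or 4 (0.0714). The camera call of the list (adjusted p = 0.0426, and adjusted p = 0.80 with an estimated correlation) was lost without wild-type replicate 1 (0.0617) or 2 (0.0835) and without knockout replicate 1 (0.0734), 3 (0.0934) or 4 (0.0619). It was also lost with quantile normalization (camera adjusted p = 0.0974), with signal on all 8 arrays (0.0636), with median scaling (0.323) and by fry (0.149). Of 14 erythroid markers Gata1 rose by 1.19 (SE 0.28), Hemgn rose by 0.71 (SE 0.10) and Epb42 fell by 0.88 (SE 0.31), and the list did not pass (camera adjusted p = 0.215, and 0.0025 upward without the filter on dim probes), though 10 members rose with median scaling. The Epb42 call was lost without any 1 of 6 arrays (limma adjusted p of 0.0569 without wild-type replicate 2, 0.0821 without 3 and 0.0673 without 4, and 0.0732, 0.0706 and 0.0705 without knockout replicates 1, 2 and 4). It was also lost with median scaling, where Epb42 differed by -0.27 (0.458), with array weights (0.0616) and with the Y-linked covariate (0.0873). Of 15 yolk sac and visceral endoderm markers only Sox17, which endothelium also expresses, passed, at 2.13 (SE 0.15). The yolk sac list did not pass (camera adjusted p = 0.513, and 0.0227 upward without the filter on dim probes), and its median of -0.37 lay below 0 although the camera direction was upward.

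**Figure D3:**
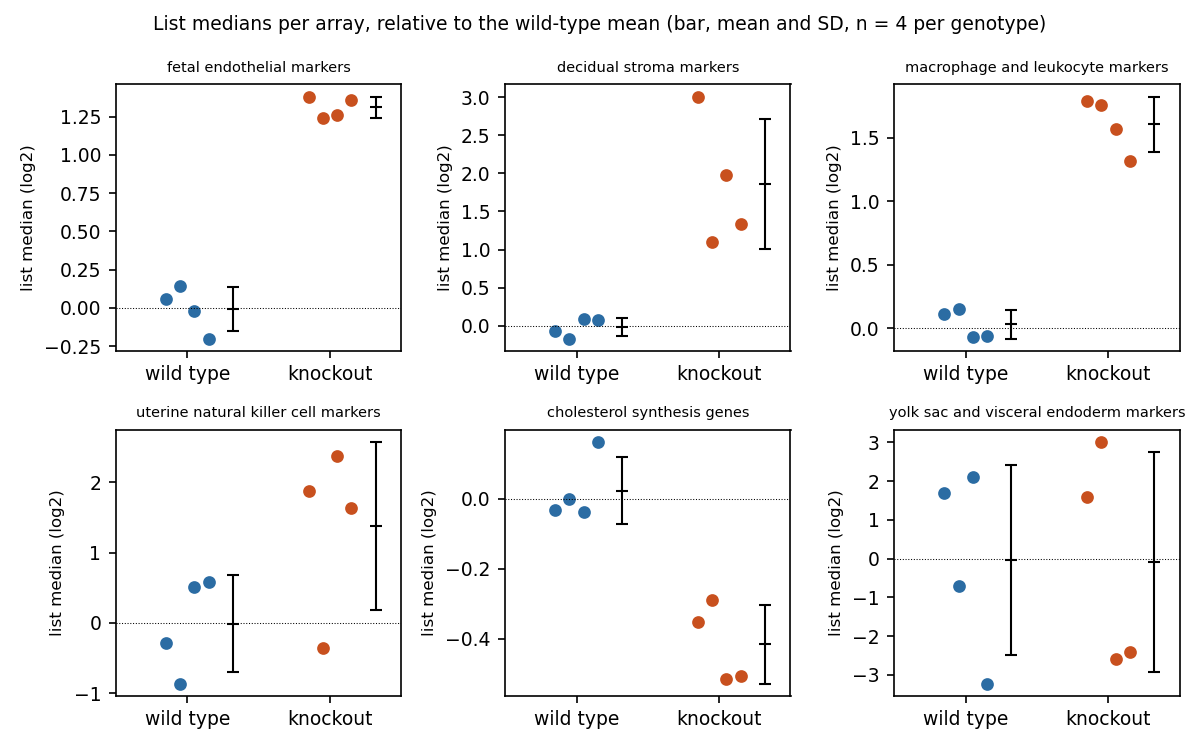
Median log2 level of the members of 6 lists on each array, relative to the wild-type mean of the members (y axis, a separate scale per panel), by genotype (x axis); points are arrays and bars the mean and SD of 4. The endothelial medians of the knockout arrays lay between 1.24 and 1.38, the natural killer medians overlapped, and the yolk sac medians spanned -3.23 to 3.02 over both genotypes.

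The trophoblast lists moved in mixed directions. Of 17 labyrinth syncytiotrophoblast markers, which cover the exchange layer, 10 rose and 4 fell, with a median of 0.73 (camera adjusted p = 0.0360, and adjusted p = 0.639 with an estimated correlation). The transcription factor Cebpa rose by 1.72 (SE 0.26) and the monocarboxylate transporter Slc16a3 rose by 1.48 (SE 0.19), while the related transporter Slc16a1 fell by 1.67 (SE 0.20) and the amino acid transporter Slc38a4 fell by 0.71 (SE 0.10). Lifr and Tfrc also fell, by 1.20 and 1.03. The labyrinth call was lost without knockout replicate 4 (camera adjusted p = 0.0580), with the Y-linked covariate (0.0568), with quantile normalization (0.121) and with median scaling (0.323), where 12 rose and 2 fell.

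In the spongiotrophoblast list, the endocrine layer of the placenta, 4 of 16 genes rose and 3 fell, against 8 and 1 with median scaling. Prl8a6 and Phlda2, an imprinted growth regulator, rose by 3.87 and 1.60 (SE 0.74 and 0.24), and Prl7b1 and Prl3c1 by 0.92 and 1.19. Tpbpb and Tpbpa, the classical markers of the layer, fell by 1.28 (SE 0.26) and 1.19 (SE 0.32), and Ascl2 fell by 0.76 (SE 0.20). Among 11 giant cell genes, of which 3 rose and none fell with median scaling, the prolactin-family gene Prl2a1 rose by 0.94 (SE 0.16), and Serpinb9g, Ctsj and Serpinb9e fell by 0.69, 0.54 and 0.48 in turn. The differences of Ctsj and Serpinb9e turned to 0.06 and 0.13 with median scaling, which also ended the calls of Serpinb9g, Ascl2, Pygl, Psg22, Psg29 and Slc38a4. Of 12 glycogen trophoblast genes 3 rose (Cdkn1c by 0.81, Igf2 by 0.67, Prl7b1) and 2 fell, as Prl6a1 fell by 1.82 and Pygl fell by 0.61, against 9 and 1 with median scaling. In the Psg and Ceacam family, secreted and membrane glycoproteins of trophoblast, 4 of 20 members fell and none rose, against 2 falls with median scaling. Ceacam3 fell by 2.94 (SE 0.31), Ceacam9 by 1.48 (SE 0.18), Psg22 by 1.30 (SE 0.42) and Psg29 by 0.89 (SE 0.21). The Psg22 call was lost without wild-type replicate 3 (limma adjusted p = 0.052) or 4 (0.0629) and with replicate number as a block (0.0529). The progenitor list held 3 rises, Ly6a by 2.42, Ly6e by 0.89 and Tead4 by 0.86, and 4 falls (7 and 3 with median scaling): Cdx2 fell by 1.28, Sox21 fell by 1.13, Met fell by 1.03 and Tfap2c fell by 0.39. Sox21 differed by -1.13 by its brightest probe and by 0.42 by the other. None of these 5 lists passed over all tested genes with 75th percentile scaling, with camera adjusted p of 0.365, 0.965, 0.790, 0.513 and 0.776 in the order given. The Psg and Ceacam list passed downward with median scaling (camera adjusted p = 0.0454), and the spongiotrophoblast list upward without the filter on dim probes (0.0031). The glycogen median of -0.12 lay below 0 although the camera direction was upward.

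Among pathway lists, 13 of 22 apoptosis genes rose and 2 fell, with a median of 0.61 (camera adjusted p = 0.00045, and adjusted p = 0.175 with an estimated correlation). The pro-apoptotic BCL2-family genes Bbc3, Bik, Bak1 and Bad rose by 1.63 (SE 0.17), 1.34 (SE 0.11), 1.04 (SE 0.11) and 0.81 (SE 0.12), while Casp3 fell by 0.45 and Apaf1 fell by 0.30. With median scaling 19 rose and none fell. Imprinted genes showed 17 rises and 7 falls among 38, with a median of 0.65 (camera adjusted p = 0.0033, and adjusted p = 0.426 with an estimated correlation). Cd81 rose by 1.94 (SE 0.12), Kcnq1 by 1.89 (SE 0.14), Ndn by 1.38 (SE 0.13) and the cell cycle inhibitor Cdkn1c by 0.81 (SE 0.08). With median scaling 27 rose and none fell, but the imprinted list did not pass (camera adjusted p = 0.0557), nor did it among genes with a symbol only (0.123). The interferon-stimulated list held 8 rises and no fall among 14 genes, with a median of 1.01, or 0.94 with the member not well above background in wild type at its bound (camera adjusted p = 0.0016, and adjusted p = 0.631 with an estimated correlation). The transcription factor Irf7 rose by 1.71 (SE 0.13), Oas1a by 1.18 (SE 0.18), Oasl2 by 1.13 (SE 0.17) and Bst2 by 0.96 (SE 0.15). With median scaling 13 rose and none fell. Immediate early and heat shock genes held 8 rises and no fall among 11 (median 0.85, camera adjusted p = 0.0047, and adjusted p = 0.426 with an estimated correlation). All 8 were immediate early or stress-response genes, among them Ier3 at 1.38 (SE 0.25), Junb at 1.36 (SE 0.11), Atf3 at 1.33 (SE 0.21) and Dusp1 at 0.91 (SE 0.15), and the members that did not pass were Fosb (0.12), Hspa1a (-0.53) and Dnajb1 (0.09). With median scaling 9 of the 11 rose, but the list did not pass (camera adjusted p = 0.0603).

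Other pathways held falls or went both ways, and none of the lists in this paragraph passed under camera over all tested genes with 75th percentile scaling. Cholesterol synthesis genes had 8 falls and no rise among 15, including Idi1 by 1.55 (SE 0.14), Cyp51 by 1.35 (SE 0.12), Hmgcs1 by 1.20 (SE 0.09) and the rate-limiting enzyme Hmgcr by 0.71 (SE 0.11), whose difference was -0.099 with median scaling (limma adjusted p = 0.469). The camera adjusted p was 0.181, but the list passed downward with quantile normalization (0.0447) and among genes with a symbol only (0.0334), and 5 rose and 3 fell with median scaling. Cell cycle genes had 9 falls and 2 rises among 25 (camera adjusted p = 0.513), with Bub1 at -1.60 (SE 0.13), Kif11 at -1.52 (SE 0.14), Mki67 at -1.39 (SE 0.12) and Ccna2 at -1.05 (SE 0.10), and 15 rises and 6 falls with median scaling. Of 19 Polycomb genes 9 fell and 2 rose (camera adjusted p = 0.530, and 2 falls and 10 rises with median scaling). Suz12 and Ezh2, core subunits of the complex that methylates histone H3, fell by 1.47 (SE 0.12) and 1.13 (SE 0.11), and Phc2 and Ezh1 rose by 0.92 (SE 0.11) and 0.66 (SE 0.08). In the microRNA machinery, Tnrc6a, Dicer1, Dgcr8 and Drosha fell by 1.02, 0.92, 0.66 and 0.40, and 5 of 13 rose, Ago4 by 0.83, Ago1 by 0.53, Tnrc6c and Tarbp2 by 0.50 and Prkra by 0.42 (camera adjusted p = 0.513), against 8 rises and 2 falls with median scaling, where Dgcr8 differed by -0.048 (limma adjusted p = 0.705). Of 28 tumour suppressor genes 12 rose and 10 fell (camera adjusted p = 0.326, and 18 and 4 with median scaling), with Cdkn2b at 1.18 (SE 0.09), Brca2 at -1.26 (SE 0.11) and Atm at -1.38 (SE 0.14). Of 19 hypoxia and glycolysis genes 8 rose, including Vegfa by 1.13 (SE 0.15), Ndrg1 by 0.98 (SE 0.11) and Aldoa by 0.69 (SE 0.08), and 4 fell, Ero1a by 1.58 (SE 0.15) the most (camera adjusted p = 0.0811, and 13 rises and 1 fall with median scaling). The hypoxia list passed upward with normexp (camera adjusted p = 0.0326). Without the filter on dim probes the hypoxia (0.00021), tumour suppressor (0.00135) and microRNA machinery (0.0239) lists passed upward. They were then set against genes with a median of -0.81 in place of -0.14. Unfolded protein response genes held 5 rises and 6 falls among 14 (camera adjusted p = 0.754), against 5 and 1 with median scaling, and the list's median of -0.35 and mean of 0.15 differed in sign. Chac1, Trib3, Derl1 and Xbp1 rose by 3.05, 2.07, 1.03 and 0.64, and the chaperone Hspa5 fell by 0.81.

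**Figure D4:**
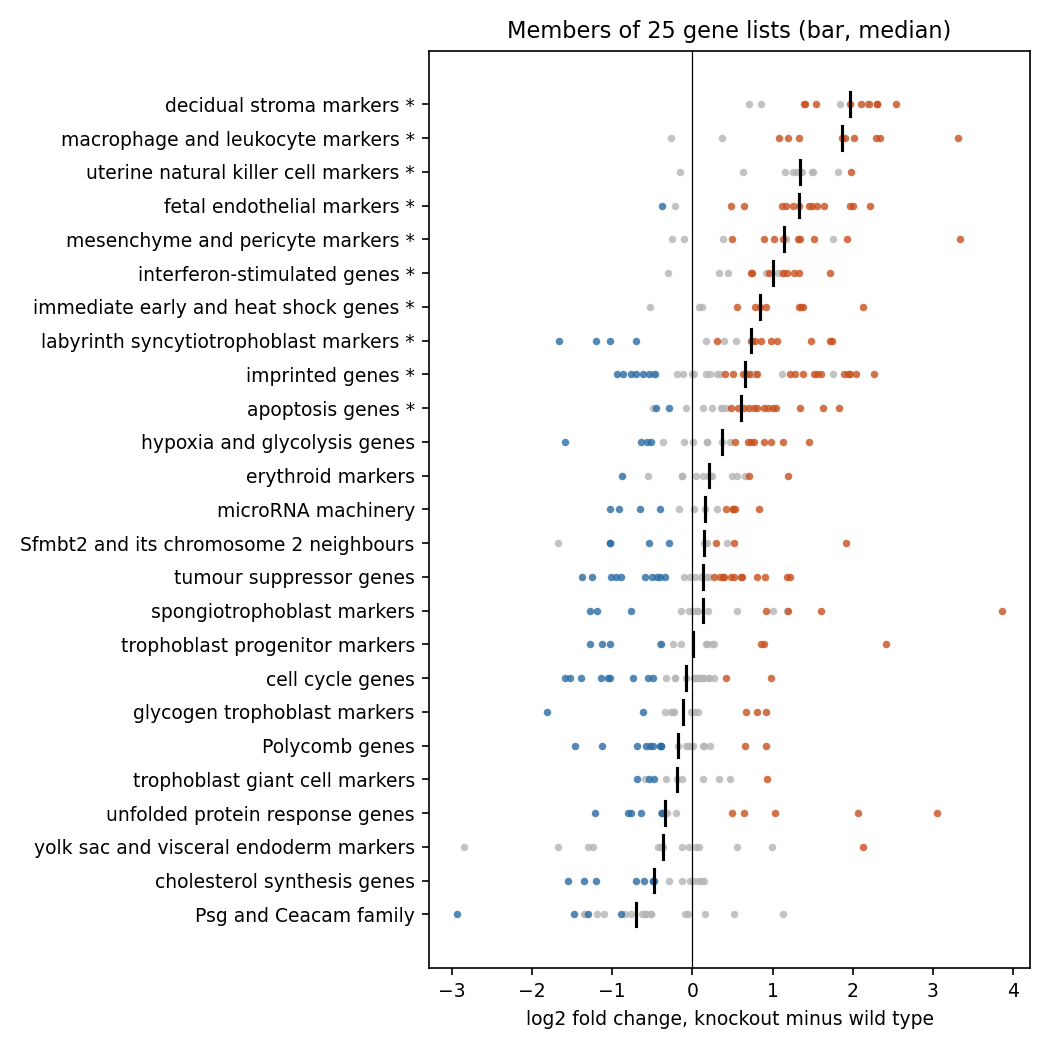
Log2 fold change, knockout minus wild type (x axis), of each tested member of 25 gene lists (y axis), with 1 point per gene, orange for higher, blue for lower and grey for not past the threshold; black bars are list medians and stars mark the 10 lists with camera adjusted p under 0.05. The decidual stroma median of 1.97 was the highest and the Psg and Ceacam median of -0.70 the lowest.

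In all, 10 of the 25 lists shifted upward and none downward under camera with a preset correlation, and no list passed with a correlation estimated from the data, where 3 had an unadjusted p under 0.05. With median scaling 5 lists passed, 4 upward and 1, the Psg and Ceacam family, downward (camera adjusted p = 0.0454). Every list member had a symbol, and the median difference was 0.11 among genes with a symbol and -0.49 among those without. Camera over all genes thus set the lists against a partly lower set, which favours upward calls. Among genes with a symbol only, 5 lists passed upward and 1, cholesterol synthesis, downward. There the lists of labyrinth (camera adjusted p = 0.262), mesenchyme (0.0543), natural killer cells (0.245), imprinted (0.123) and immediate early genes (0.0634) lost their call. Among bright genes only those of fetal endothelium and apoptosis kept theirs. Adjusted over the list alone, the counts of rises and falls were 0 and 0 for natural killer cells, 7 and 0 for interferon-stimulated genes, 0 and 3 for the Psg and Ceacam family, 2 and 0 for erythroid and 1 and 9 for cell cycle genes. The counts of the other 20 tested lists were the same as over all genes. By fry, which asks only whether a list's genes move one way on balance, 14 lists passed, 10 upward and 4 downward. The downward lists were those of cholesterol synthesis (adjusted p = 0.00018), Polycomb (0.0023), trophoblast progenitor (0.0277) and cell cycle genes (0.0367). Members of the lists named here beyond the 4 of smallest p were chosen after their values were seen.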

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

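The tests of explanations in this part, the splits of the arrays and the alternatives with bright genes only and, for lists, median scaling were chosen after the results were seen. Normexp and, for gene counts, median scaling had been fixed before as alternatives.

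The first pattern was the size of the genotype difference, 17965 of 26983 genes, and its excess of falls, 10849 against 7116. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, called as many genes (the highest other called 1). For genes of at least 2-fold it was also 1 (7240, the highest other 1). Every other split mixes the genotypes, so the difference between them widens the spread within its groups and few calls must follow. The splits therefore cannot decide on chance for either count. The difference in background of dim spots is argued against as the whole cause of the size, since 67.61% of bright genes were called. Among bright genes 4289 rose and 3450 fell, so the excess of falls lay among the dimmer genes. The scaling point moves all genes alike and so cannot be tested against them (75.06% of calls were rises with median scaling). The cause of the excess of falls among dimmer genes stays open. Scan session and slide cannot be told apart from genotype, since no session held both, and an effect of the deletion stays open beside them. The spike-in and negative controls are not transcripts of the samples, yet they differed between the sessions, so a technical difference was present. Relative to the 75th percentile, spike-in differences ran from -2.04 to 2.16, with 0.87 for the brightest, so no single scaling point removes them all. Its part in the gene differences was not measured. Between the wild-type slides 6 genes differed, but those slides also divide the arrays with and without Y-linked signal.

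The second pattern was the rise of decidual stroma markers (median 1.97) and macrophage markers (median 1.87) in samples whose deciduas had been removed. A background difference of dim spots as the whole cause stays open. Both lists, 2 of 2, passed with normexp (medians 1.51 and 1.45). Normexp used the local background, with a median of 36.0 ± 1.4 on wild-type and 48.1 ± 3.2 on knockout arrays (SD, n = 4 each). The negative controls differed the other way, so passing with normexp cannot decide on that cause. Neither list passed among bright genes (camera adjusted p = 0.214 and 0.105), where 5 of 13 and 3 of 11 members were left to test. Those members had medians of 1.40 (0.70 to 1.97) and 1.90 (1.34 to 2.35). Over all members the differences ran from 0.70 to 2.54 and from -0.27 to 3.32. Maternal tissue may be a source and was not measured. On all wild-type arrays 12 of the 13 decidual and 10 of the 11 macrophage markers were well above background, which does not tell maternal from placental expression. The most abundant were Prl8a2 (7.71 in knockout, 6.31 in wild type) and Csf1r (7.36 and 6.03). Csf1r stood far above the next macrophage marker, Fcer1g (2.46 and 0.56), so its level need not follow macrophages. Xist in the 1 knockout array with Y-linked signal lay below background. This allows up to 3.92% of the level of the other knockout arrays and leaves a small maternal share open in that array. The other 3 knockout arrays had Xist well above background themselves, so Xist sets no limit on maternal tissue in them. Session cannot be told apart from genotype (the smallest gap between a knockout and a wild-type decidual median was 1.01 on the log2 scale), and a change in the placenta itself was not tested.

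The third pattern was the rise of 13 of 15 fetal endothelial markers. The members did not rise alike, since the 95% intervals of 7 of the 15 left out the list median of 1.33. Of these 4 lay below and 3 above it, with Kdr among those below by 1 probe of 2. A larger endothelial share as the only change predicts an equal rise only for markers of endothelium alone and probes that respond alike. Neither condition was tested, so the intervals cannot decide on that explanation. A background difference as the whole cause is argued against, as the list kept its call among bright genes (camera adjusted p = 0.00312). A change in endothelial share, alone or together with other changes, and session could each account for the rise and stay open. Of the 35 splits, 13 gave as many lists past the threshold as the genotype split (10, the highest other 12), so chance cannot be excluded for the number of lists.

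One array stood apart from the other 3 of its genotype in 18 of 274 groups of 4, where chance gives about 13.7, and 6 of the 18 were knockout replicate 4. The measure is the gap to the nearest array over the whole range, set against Dixon's critical value for 4 arrays. Knockout replicate 4 stood above the others for Myh4 (0.969), Slc16a1 (0.934), Pygl (0.923) and Ago4 (0.9), and below them for Junb (0.937) and Hemgn (0.904). Knockout replicate 2 was low for Psg29 (0.909) and Egfl7 (0.867) and high for the mesenchyme list (0.848). Knockout replicate 3 was low for Vegfa (0.913) and Irf7 (0.841) and high for the erythroid list (0.921), and knockout replicate 1 was low for Pfkfb3 (0.899). Wild-type replicate 4 was low for Mki67 (0.925), Bub1 (0.861) and Brca2 (0.849) and high for Serpinb9g (0.85), and wild-type replicate 2 was low for Hoxa10 (0.899). The median spike-in signal, used in no comparison, was 3.04-fold higher on the knockout arrays (2214 against 728), where 8 of the 10 controls were brighter and 2 dimmer. Relative to each array's 75th percentile, the log2 spike-in median was 0.15 to 0.25 on wild-type arrays and 2.11 to 2.21 on knockout arrays. Scaling to that median would move every difference down, opposite to median scaling, and was not run.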

How the results depend on the processing

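The alternatives with bright genes only, genes with a symbol only, centring on the tested probes and, for lists, median scaling and signal on all 8 arrays were chosen after the results were seen. Signal over background limits the dim genes. Leaving out each array gave 16472 to 17641 genes, 6796 to 7412 of at least 2-fold, a Sfmbt2 difference of -0.60 to -0.49 and 8 to 10 lists. With replicate number as a block there were 17635 genes, 7253 of at least 2-fold and 10 lists, and the Sfmbt2 difference was -0.54 (adjusted p = 0.0109). The numbers do not pair the arrays (correlations of 0.116, 0.118, -0.125 and 0.297). Of the 111 named genes other than Sfmbt2, 109 kept their direction and call with normexp, 110 with quantile normalization and 99 with median scaling. Most of them had been chosen by the size or p of their difference in these data, which favours keeping the call. Of all 17965 called genes, 16805, 15401 and 11905 kept direction and call with these settings in turn.

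Without a filter 35452 genes differed and 23838 by at least 2-fold, and 16 lists passed, set against genes with a median of -0.81 in place of -0.14. With fewer genes tested there were 7739 and 1562 (bright genes only, 2 lists) and 9812 and 3465 (symbol only, 6 lists). Normexp gave 2905 genes of at least 2-fold, median scaling 5 lists and an estimated correlation 0 lists; the cause was not tested. The Sfmbt2 difference was 0.070 with median scaling, -0.33 as the mean of its probes and -0.37 and -0.095 by the other probes; the cause was not tested.

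The lists that turned did so as follows, in mean z of members minus that of other genes, none past the threshold but progenitor by fry; the cause was not tested. Normexp: giant cell 0.18. Quantile: chromosome 2 neighbours -0.15, glycogen -0.43, progenitor -0.089, unfolded protein response -0.12. Median scaling: giant cell 0.17, yolk sac -0.93, Polycomb 0.38. No filter: giant cell 1.16, Psg and Ceacam 0.53, cell cycle 0.46, Polycomb 0.71. Y-linked covariate: giant cell 0.048. Bright genes: chromosome 2 neighbours -1.13, glycogen -0.41, microRNA machinery -1.93, unfolded protein response -0.61. Symbol only: chromosome 2 neighbours -0.47, glycogen -0.53, progenitor -0.47, yolk sac -0.10, microRNA machinery -0.00043, unfolded protein response -0.41. By fry, in the members' own mean z: chromosome 2 neighbours -0.24, glycogen -0.31, progenitor -0.24 (adjusted p = 0.0277) and microRNA machinery 0.22 with a downward test. Leaving out each array took the giant cell list from -0.18 to 0.16. Among genes, Xist was 0.51 with quantile normalization, 0.61 with median scaling, 0.019 in the deposited table, 0.029 centred on the tested probes, -2.88 with the Y-linked covariate (adjusted p = 0.0052) and -1.41 to 1.39 without each array, and Ctsj was 0.065 and Serpinb9e 0.13 with median scaling. The planned seed-site alternatives were not run.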

Other observations

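The yolk sac and visceral endoderm markers, which include the serum proteins Afp, Apoa1 and Ttr, varied between samples of one genotype more than between genotypes. Relative to the wild-type mean, their median was 1.69, -0.71, 2.10 and -3.23 in wild-type replicates 1 to 4 and 1.60, 3.02, -2.59 and -2.42 in knockout replicates 1 to 4. Afp differed by -1.31 between genotypes (SE 2.43, limma adjusted p = 0.652).

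Sex-linked transcripts also varied within genotype. Xist, the RNA that coats the inactive X chromosome, was well above background in wild-type replicates 1 and 2 and knockout replicates 1, 2 and 3. The Y-linked genes Ddx3y and Eif2s3y were well above background in wild-type replicates 3 and 4 and knockout replicate 4, where Ddx3y stood at 1.51, 1.35 and -0.51. The Y-linked list was not tested, as no member passed the filter. Xist differed by -0.0025 between genotypes (SE 1.98), but by -2.88 with the mean Y-linked level as a covariate (limma adjusted p = 0.0052). On arrays without Y-linked signal that level was -6.65 and -6.64 in wild type and -7.76 to -7.92 in knockout. The covariate thus differed with genotype below background, and -2.88 is not a sex-matched difference. Where Xist was well above background, it stood at 0.81 and 0.77 in wild type and at -0.49, -0.71 and -1.53 in knockout. Afp and Ddx3y were chosen after their values were seen. With that covariate 16713 genes differed and 9 lists passed.

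Between probes of one gene, across 3890 genes with more than 1 probe, the differences correlated at 0.66, and genes are not independent replicates. Both probes were called for 1813 of these genes, with opposite signs for 181, or 9.98%. Where both probes were at or above the 75th percentile, the correlation was 0.784 and 6.69% were opposite.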
